A study of Mus musculus with 4 samples.

How the data were processed

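Total RNA of Rap1a knockout mouse microvascular smooth muscle cells with an empty or a RapCA shuttle vector was labelled with Cy5 or Cy3 and hybridised in pairs to 4 two-colour Agilent arrays on 1 slide, per the labels. Slide therefore cannot be examined as a batch. The arrays were scanned and read with Agilent Feature Extraction, version 10.7.3.1 per the file headers and 10.9 per the submitters' processing notes. The intensity values used here, deposited in the scanner files, are the median pixel brightness of each spot and of its local background in each channel, with no normalization, per the file headers. The log10 values deposited in the scanner files and in the series table are ratios of Cy5 over Cy3 after background subtraction, detrending and dye normalization by Feature Extraction, per the file headers. The series table differed from the scanner files' log10 ratio by at most 5e-05 over 40929 probes with 1 spot, and the median of each of its columns was 0. The analysis had been planned on mean spot signals, which the files do not hold, so median signals were used.

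Background was corrected with normexp and an offset of 50, and ratios were normalized by loess within each array with control spots given no weight. Spots that the scanner software marked as outliers (122, 110, 94 and 137 on replicates 1 to 4) were left out, and spots of a probe were averaged over 43379 non-control spots. No spot was saturated. The median net signal was 37, 83.5, 81 and 75.5 in Cy5 and 43, 43, 35.5 and 40.5 in Cy3 on replicates 1 to 4, and the median SD of a probe over arrays was 0.25 log2 units. Probes were kept when well above background on all 4 arrays in at least 1 channel, which left 23497 of 41174. Ratios are log2 of Cy3 over Cy5, that is of the channel labelled RapCA over the channel labelled vector. Gene symbols came from a RefSeq table by accession and were found for 64.8% of probes, covering 18217 genes; 12388 genes were tested. The files name another genome build than that table, so only names were used and no probe was placed on a gene.

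The mean ratio was tested against 0 with limma (lmFit and eBayes) and called at a Benjamini-Hochberg adjusted p under 0.05, with at least 3 arrays per probe. The ± values are SDs over arrays. Gene lists, 26 of pathways and 8 of cell type markers, were tested with limma's camera with a preset inter-gene correlation of 0.01, using the brightest probe of each gene and lists of at least 5 measured genes (33 of 34). Beside these stand camera with an estimated correlation and counts of members adjusted over the list alone. For a gene not above background in 1 channel on any array, the fold is given as a lower bound. The tests, lists, alternatives and named genes were chosen before the data were examined. Named were Rap1a, Rap1b, Adra2c, Flna and Flnc, the 15 largest rises and 15 largest falls among called probes with a symbol and the same sign on all arrays, and up to 4 members of each list with the smallest p. A few genes and 1 list that this rule or plan covers are not reported here, but were kept in every test and count.

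The limma scripts were tested on simulated data, with 200 of the 23497 probes changed. With the moderated SD of the real fit as spread, 16%, 68%, 94% and 92% of changes of log2 0.5, 1, 2 and 4 were recovered, with 5 false calls and median fitted sizes of 0.41, 0.86, 1.81 and 3.50. With unmoderated SDs, which were tried first, recovery was 12%, 36%, 72% and 76% with 2 false calls. The moderated spread was adopted after that lower recovery had been seen. In the real data 49.6% of probes were called, which moves the cutoff on p, so the simulated shares do not give the recovery there. The simulated Cy3 signal was built from the Cy5 signal of the same spot, so no dye trend with intensity was put in. Removal of such a trend by loess was therefore not tested. Nor was loess tested with so many probes changed, or with an array that stands apart. A matrix list shifted by log2 1 was found (camera adjusted p = 8.01e-08) and none of 30 lists sharing no gene with it was called. Noise was drawn independently for each gene there. In the real data the estimated correlation was 0.51 for the cell cycle list and 0.64 for pericyte markers. False calls of lists whose genes vary together were therefore not tested. The alternatives tried covered background correction, centring, the scanner software's ratios, the series table, filters, outlier spots, variance models, array weights, separate channels, no pairing of channels, turned signs, each array left out, list tests and genes in place of probes. Analysis used R 4.3.3 with limma 3.58.1, statmod 1.5.0 and the package data.table (version 1.17.8), and figures used Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.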

Results

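Gene expression was measured in mouse microvascular smooth muscle cells labelled as Rap1a knockout. Rap1a is a small GTPase of the Ras family that acts in cell adhesion and junction signalling. Cells carrying an empty shuttle vector were set against cells carrying a vector named RapCA in the labels, a name that the labels do not spell out. The series title calls the comparison a knockout against a rescue, so the question it addresses is which transcripts differ between cells given the empty vector and cells given the vector named RapCA. All cells were from male C57BL6 mice and received virus overnight in serum-free medium at plating. They then recovered for 48 h in medium with 0.5% serum, after growth in 10% serum. Each of 4 two-colour whole-genome arrays held 1 RNA of each kind, and the labels call the 4 arrays biological replicates without saying whether these were separate cultures or animals. On every array the labels put the empty vector in the Cy5 channel and RapCA in the Cy3 channel, so no array has the dyes exchanged and dye and condition cannot be told apart. The share of probes well above background was 57.7% to 62.9% in Cy3. In Cy5 it was 60.1% to 61.9% on replicates 2 to 4 and 51.3% on replicate 1. The log2 ratios of replicate 1 correlated with those of the other arrays at 0.69 to 0.78 across 23485 probes, against 0.93 to 0.98 among the other 3; probes are not independent replicates.

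The targeted gene went against the labels. The 1 Rap1a probe measured was well above background in both channels on all 4 arrays, and its signal was lower in the channel labelled RapCA than in the channel labelled vector, at a log2 ratio of -1.07 ± 0.44 (SD, n = 4; limma adjusted p = 0.00204). The ratios were -0.46, -1.02, -1.31 and -1.47 on replicates 1 to 4. Its mean log2 level was 11.7 in the channel labelled RapCA and 12.7 in the channel labelled vector. So strong a signal in cells labelled as knockout also goes against the labels, unless the probe lies outside the deleted part of the gene. Where the probe lies relative to that part, or to any sequence the vector carries, is not known here, so the probe may not check the labels at all. Every direction below therefore follows the dye labels only, and channels are named as labelled. A positive log2 ratio means more signal in the channel labelled RapCA. If the dyes were recorded the wrong way round, every sign below turns. Rap1b, the close paralogue of Rap1a, had a ratio of 0.80 ± 0.54 (adjusted p = 0.0134), and its ratio on replicate 1 was 1.55 against 0.32 to 0.80 on the others. It did not pass with median centring (adjusted p = 0.313).

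The channels differed across much of the transcriptome. Most genes tested in the extracellular matrix and sterol synthesis lists were higher in the channel labelled RapCA, and most in the interferon response and cell cycle lists were lower. Camera with a preset correlation called 13 of 33 lists, and with an estimated correlation 0. With only 4 arrays the version with an estimated correlation can hardly call any list, so a lost call does not show that correlated genes had made it. The SRF and YAP, heat shock and Notch lists had estimated correlations of -0.024, -0.013 and -0.010, below the preset, and lost their calls too. All other called lists had estimates above the preset, from 0.037 (interferon response) to 0.51 (cell cycle) and 0.64 (pericyte markers). Their p-values with the preset may therefore be too small. The test fry, which sets a list against no change in place of other genes, called 26. A list is named as called below when camera with a preset correlation called it. By the brightest probe of each gene, 3582 of all 12388 genes tested were higher and 3090 lower, so 53.9% passed. Counts of list members in both directions together are to be read against that share. Counts in 1 direction are to be read against the 3582 higher or the 3090 lower of 12388. Of 23497 probes tested, 11654 passed an adjusted p of 0.05, with 6207 higher and 5447 lower in the channel labelled RapCA. A change of at least 2-fold was seen at 3092 probes, 1723 higher and 1369 lower, and 43 were at least 8-fold higher and 51 at least 8-fold lower. The 15 largest rises were led by Ccn5 at a log2 ratio of 4.31 ± 0.50, Lama4 at 4.16 ± 0.25, Gas6 at 4.12 ± 0.23 and Svep1 at 4.05 ± 0.55. The largest falls were those of the proliferin genes Prl2c5 and Prl2c3, at -5.82 ± 0.47 and -5.80 ± 0.49, which are near-identical relatives whose signals cannot be separated here. They were followed by Cxcl10 at -5.23 ± 0.16 and Rsad2 at -5.22 ± 0.25. Centring each array on its median in place of an intensity-dependent fit called 6546 probes, of which 40.1% were higher against 53.3% in the first analysis, and moved the median of all probes from 0.01 to -0.14. With the scanner software's ratios 5286 probes changed at least 2-fold, and with array quality weights 17694 probes were called. Leaving out replicate 1 raised the number called to 15739, and leaving out replicate 2 or 3 reduced the probes called lower to 3625 and 3526.

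**Figure D1:**
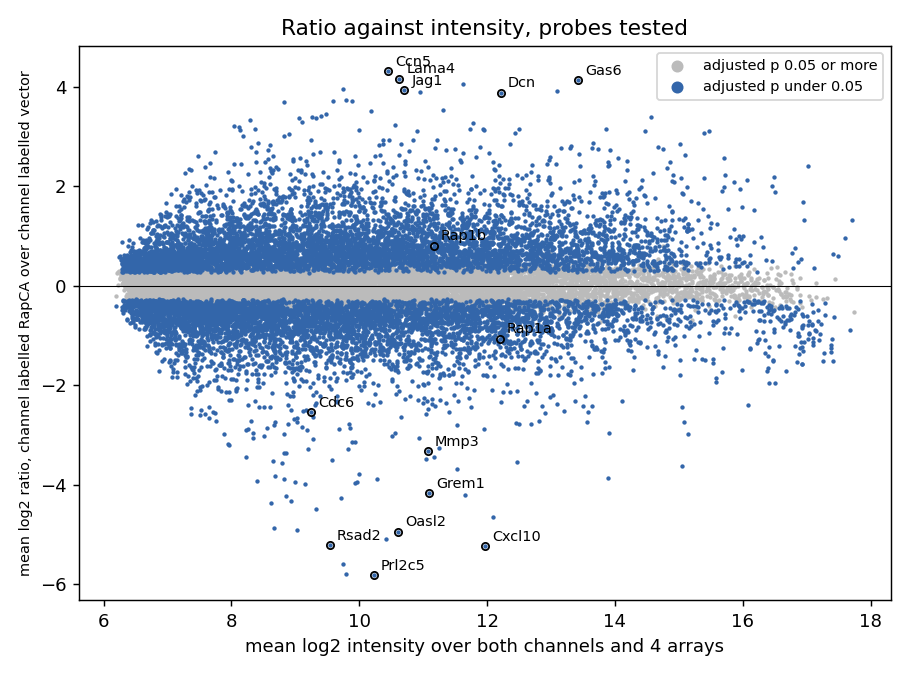
Mean log2 ratio of each probe tested (channel labelled RapCA over channel labelled vector, 4 arrays) against its mean log2 intensity over both channels. Blue points are the 11654 probes with an adjusted p under 0.05 and grey points the rest; named probes are circled, with Ccn5 highest at 4.31 and Prl2c5 lowest at -5.82.

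Interferon response genes, which cells switch on after viral nucleic acid or interferon, formed the group with the largest difference. Of 38 tested, 37 were lower in the channel labelled RapCA and none was higher, 33 of them by at least 2-fold, with a median log2 ratio of -2.67. Cxcl10, an interferon-induced chemokine, and Rsad2, an antiviral enzyme, stood at -5.23 and -5.22. Oasl1 and Oasl2, antiviral relatives of the oligoadenylate synthetases, stood at -5.09 ± 0.40 and -4.95 ± 0.19. Rtp4 and Ifi44, also interferon-induced and among the 15 largest falls, stood at -4.64 ± 0.35 and -4.34 ± 0.68. The list passed camera with a preset correlation (adjusted p = 1.55e-19) but had an adjusted p = 0.186 with an estimated correlation. The count adjusted over the list alone was also 37. Among the 21 inflammatory cytokines and chemokines tested, 11 were lower and 6 higher (17 when adjusted over the list alone), and the list was not called (adjusted p = 0.0681), but was with the scanner software's ratios (0.0425), a smaller offset (0.0449) and fry (0.00125). With median centring 9 were lower and 1 higher. With both channels above background on all arrays 7 were lower and 6 higher (camera adjusted p = 0.249). Its lower members included Ccl5 at -4.22 ± 0.68, the prostaglandin synthase Ptgs2 at -2.86 ± 0.75 and Saa3 at -1.85 ± 0.23, the last above background on 2 of 4 arrays in the channel labelled RapCA. Cxcl10 belongs to both lists.

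Cell cycle genes were lower in the channel labelled RapCA at 34 of 37 tested, with 1 higher, 30 lower by at least 2-fold and a median of -1.28. The replication licensing genes Cdc6 and Mcm5 had ratios of -2.55 ± 0.23 and -2.22 ± 0.20, and the mitotic activator Cdc20 had -1.63 ± 0.16. Ccnd2, which encodes cyclin D2, was the exception at 1.86 ± 0.17. Adjusted over the list alone, 36 were called. The camera adjusted p was 5.83e-12, and the adjusted p = 0.386 with an estimated correlation. Ribosomal protein genes differed less: 14 of 27 were lower and 3 higher (18 adjusted over the list alone), with a median of -0.39. Rplp1 and Rplp0 of the ribosomal stalk had -1.37 ± 0.33 and -1.10 ± 0.19, Rps18 had -0.95 ± 0.17 with a second probe that did not pass, Rpl32 had -0.71 ± 0.06, and many ribosomal protein genes have processed copies that can share a probe. That list had a camera adjusted p of 0.00799 and an adjusted p = 0.463 with an estimated correlation. The camera call was lost with the scanner software's own ratios (7 lower, median -0.19, adjusted p = 0.171). With median centring it was stronger, with 22 genes lower, none higher and a median of -1.12 (adjusted p = 1.61e-08).

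The 3 stress response lists had medians below 0 and members in both directions. In the list for unfolded protein and amino acid stress, 15 of 27 were lower and 4 higher (20 adjusted over the list alone), with a median of -0.44 (-1.001 with median centring). The endoplasmic reticulum proteins Sdf2l1, Creld2 and Pdia4 had ratios of -3.55 ± 0.34, -2.99 ± 0.16 and -1.27 ± 0.12, and the stress-induced factor Atf3 had -1.82 ± 0.05. Camera gave an adjusted p of 0.00799, and an adjusted p = 0.350 with an estimated correlation. Of 22 NRF2 and oxidative stress genes, 13 were lower and 4 higher (17 adjusted over the list alone), with a median of -0.65 (-1.03 with median centring, where 13 were lower and 1 higher). Mt2, a metallothionein, had -2.45 ± 0.28, and the glutathione enzymes Gsta4, Gsr and Gclm had -1.36 ± 0.10, -1.31 ± 0.15 and -1.18 ± 0.18. The camera adjusted p was 0.00922, and the adjusted p = 0.350 with an estimated correlation. Heat shock genes were lower at 9 of 15 and higher at 2 (12 adjusted over the list alone), with a median of -0.48 (-1.02 with median centring). Hmox1, the haem oxygenase, and Hspe1, a mitochondrial chaperonin, were lower at -1.20 ± 0.21 and -1.004 ± 0.161, while the chaperone partners Bag3 and Cryab were higher at 1.29 ± 0.04 and 1.68 ± 0.44. This list had a camera adjusted p of 0.0364 and an adjusted p = 0.350 with an estimated correlation, and its call was lost with the scanner software's ratios (adjusted p = 0.0512).

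Other large falls lay outside these lists. Grem1, a secreted inhibitor of bone morphogenetic proteins, was lower at -4.18 ± 0.24, and Blnk, a signalling adaptor of B cells, at -4.49 ± 0.13. The transcription factor gene Sox12 had -3.99 ± 0.51, and Gvin1, an interferon-inducible GTPase gene that the interferon list does not hold, had -3.96 ± 0.64. Nefl, a neurofilament gene, had -4.86 ± 0.63 and Lonrf3 had -4.36 ± 0.32. Both were above background on 1 of 4 arrays in the channel labelled RapCA and on all 4 in the channel labelled vector.

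Among lists with most genes higher in the channel labelled RapCA, extracellular matrix had the most such genes. Of 36 tested, 33 were higher in the channel labelled RapCA and 1 was lower, 25 higher by at least 2-fold, with a median log2 ratio of 1.53 (0.93 with median centring). The laminin chain gene Lama4 and the small proteoglycan genes Dcn, Prelp and Bgn had ratios of 4.16 ± 0.25, 3.88 ± 0.19, 3.54 ± 0.38 and 2.73 ± 0.23, and Col6a2 of type VI collagen had 2.64 ± 0.21. Aspn, a proteoglycan gene close to Dcn but outside the list, had 3.73 ± 0.29. Adjusted over the list alone, 35 were called, with a camera adjusted p of 4.83e-12 and an adjusted p = 0.350 with an estimated correlation. Fibroblast markers were higher in the same channel at 8 of 14 tested, lower at 2, and 10 were called when adjusted over the list alone. Their median was 0.70 (1.12 with a smaller offset and 1.76 with the scanner software's ratios), with a camera adjusted p of 0.0153 and an adjusted p = 0.463 with an estimated correlation. Dpt, Scara5 and Mfap5 had 2.76 ± 0.11, 2.28 ± 0.31 and 2.14 ± 0.27, and 2 of the 14 markers, Dcn and Pdgfra, also stand in other lists.

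Matrix proteases and their inhibitors moved in both directions, with 13 of 22 higher and 6 lower (19 adjusted over the list alone) and no call for the list (adjusted p = 0.0732), but with a call when both channels had to be above background (0.0144) and with fry (0.00322). The inhibitors Timp3 and Timp2 were higher at 2.49 ± 0.35 and 1.88 ± 0.24. The stromelysin genes Mmp3 and Mmp10 were lower at -3.33 ± 0.14 and -2.72 ± 0.42, with Mmp10 above background on 1 of 4 arrays in the channel labelled RapCA. Integrin and adhesion genes were higher at 14 of 25 and lower at 6 (20 adjusted over the list alone), also without a call (adjusted p = 0.0873), but with a call under median centring (0.0414, with 9 higher and 4 lower), no filter on dim probes (0.0418) and fry (0.000752). The collagen receptor chain Itga11 was higher at 3.90 ± 0.64 and the adaptor Pxn at 1.44 ± 0.18. The leukocyte integrin chain Itgb7 was lower at -3.82 ± 0.29 and Alcam at -2.22 ± 0.43.

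Smooth muscle contractile genes were higher in the channel labelled RapCA at 11 of 17 tested and lower at 1 (12 adjusted over the list alone), with a median of 0.68. The median was 0.39 with median centring, where 5 were higher, 0.25 with no filter on dim probes and 1.03 with the scanner software's ratios. Aoc3, an amine oxidase abundant in smooth muscle, had 2.44 ± 0.23, the actin-binding protein gene Tagln had 2.13 ± 0.28, and the myosin kinase and light chain genes Mylk and Myl9 had 1.55 ± 0.19 and 1.53 ± 0.15. The camera adjusted p was 0.000805, and the adjusted p = 0.350 with an estimated correlation. Targets of SRF and YAP, factors that respond to actin state and cell tension, were higher at 11 of 19 and lower at 1 (12 adjusted over the list alone), with a median of 0.58. Amotl2, Ccn2, Ccn1 and Cnn2 had 2.01 ± 0.11, 1.66 ± 0.14, 1.42 ± 0.17 and 1.23 ± 0.16. That list had a camera adjusted p of 0.0262 and an adjusted p = 0.350 with an estimated correlation, and the camera call was lost with median centring (5 higher, median 0.33, adjusted p = 0.0947).

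Flna and Flnc, which encode actin crosslinkers of the cell cortex, were measured with several probes each. The 3 Flnc probes gave 1.90 ± 0.26, 1.69 ± 0.14 and 0.58 ± 0.34 and all passed, the last of them no longer when replicate 2, 3 or 4 was left out (adjusted p = 0.0586, 0.0748 and 0.0530). The 3 Flna probes gave 1.40 ± 0.35, 0.65 ± 0.57 and 0.54 ± 0.13 and passed as well. None of these Flna probes passed with median centring, where the probe at 0.65 had a ratio of -0.11, and without replicate 4 that probe had an adjusted p of 0.0767. Actn1 and Arhgef2 were higher at 0.81 ± 0.08 and 1.07 ± 0.26, and the cofilin kinase Limk1 was lower at -1.02 ± 0.25. Neither Actn1 nor Arhgef2 passed with median centring (adjusted p = 0.0983 and 0.0884), and 2 of the 3 other Arhgef2 probes did not pass in the first analysis either.

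**Figure D2:**
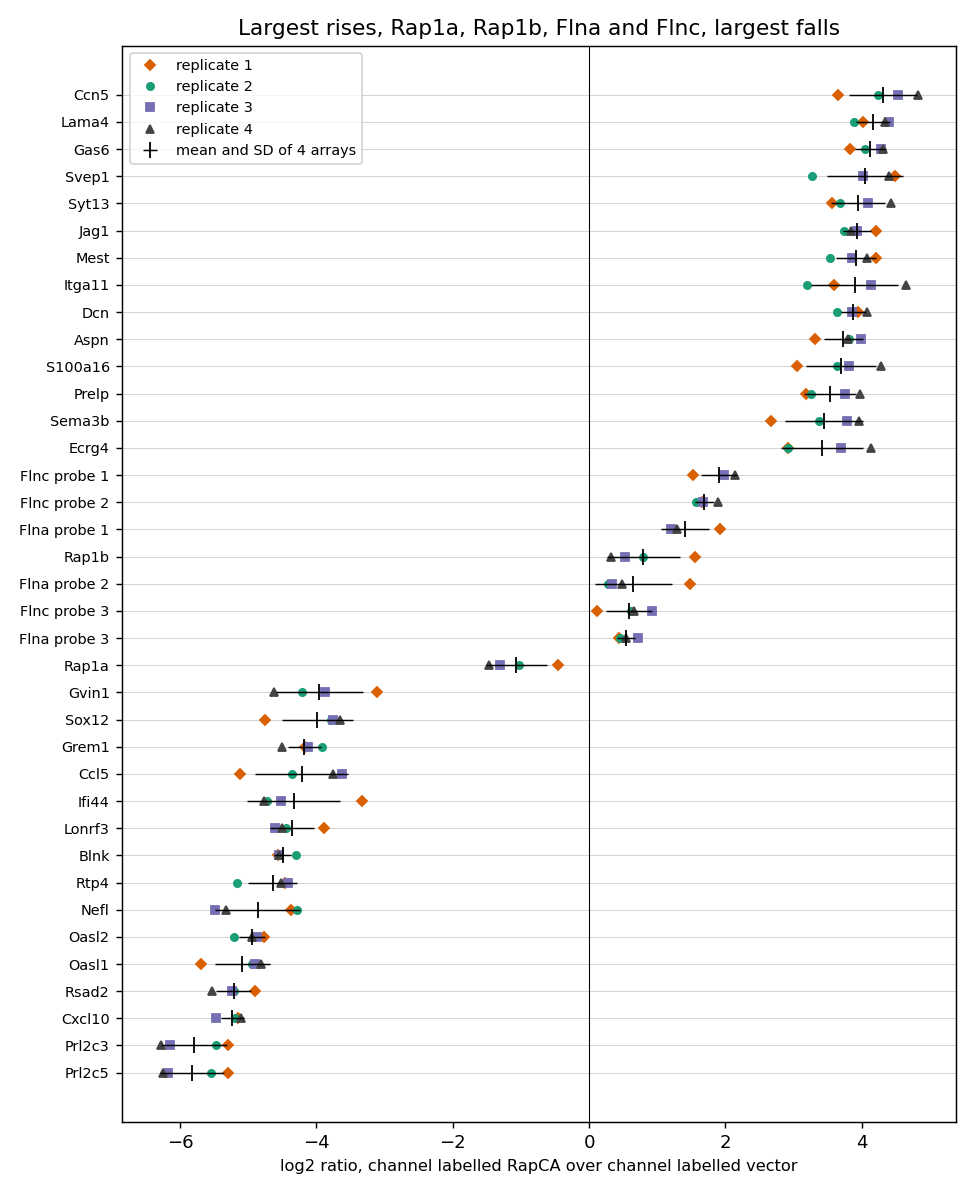
Log2 ratio (channel labelled RapCA over channel labelled vector) on each of 4 arrays for the largest rises, all tested probes of Rap1a, Rap1b, Flna and Flnc, and the largest falls; bars are the mean and SD. Rap1a lies below 0 on all 4 arrays, with a mean of -1.07, and replicate 1 lies apart from the others for Flna probe 2 (1.49).

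Genes of sterol and fatty acid synthesis were higher in the channel labelled RapCA at 20 of 26 tested and lower at none (21 adjusted over the list alone), with a median of 0.97; with median centring 11 were higher, 1 was lower and the median was 0.58. The sterol enzymes Nsdhl and Cyp51 had 1.34 ± 0.24 and 1.07 ± 0.19 (Cyp51 not passing with median centring), and the regulator Srebf1 had 1.08 ± 0.23. Of 2 other Cyp51 probes tested, only 1 was also called higher. Camera gave an adjusted p of 2.73e-05, and an adjusted p = 0.350 with an estimated correlation. Notch pathway genes were higher at 9 of 15 and lower at 1 (10 adjusted over the list alone), with a median of 0.35, which was 0.12 with no filter on dim probes, 0.64 with a smaller offset and 0.76 with the scanner software's ratios. The ligands Jag1 and Dll1 had 3.93 ± 0.20 and 1.14 ± 0.23, the receptor Notch3 had 2.79 ± 0.50 and the target Hes1 had 2.19 ± 0.29. The Notch list had a camera adjusted p of 0.0364 and an adjusted p = 0.350 with an estimated correlation. Its camera call was lost without replicate 1 (adjusted p = 0.0578), without replicate 4 (0.0570) and with both channels above background on all arrays (0.0604, 6 genes higher).

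Several signalling groups held large changes in both directions and were not called by camera. Fry called all of them. It put TGF-beta and BMP genes (adjusted p = 0.00125) and growth factors (0.00125) higher. It put immediate early genes (0.0111) and cyclic AMP targets (0.0332) lower. Among 28 TGF-beta and BMP genes, 13 were higher and 6 lower (19 adjusted over the list alone, camera adjusted p = 0.217). The latent TGF-beta binding protein gene Ltbp2 was higher at 3.40 ± 0.16, the ligand Tgfb3 at 2.88 ± 0.16 and the feedback gene Pmepa1 at 2.17 ± 0.20. Grem1, also of this list, was lower at -4.18 ± 0.24. With median centring 8 were higher and 3 lower. Of 30 growth factors and receptors, 14 were higher and 10 lower (24 adjusted over the list alone; adjusted p = 0.258), against 10 and 6 with median centring. Gas6, a ligand of the Axl receptor family, Igfbp3 and Egfr were higher at 4.12, 2.69 ± 0.42 and 2.30 ± 0.29, and Angptl4 was lower at -2.81 ± 0.42. Immediate early and MAPK feedback genes were higher at 7 of 28 and lower at 11 (18 adjusted over the list alone; adjusted p = 0.217). These counts became 2 and 11 with median centring, 4 and 8 without replicate 2, and 6 and 7 without replicate 3. Fosl1 of the AP-1 family had -3.06 ± 0.35, Phlda1 had -2.79 ± 0.18 and the MAPK phosphatase gene Dusp4 had -2.51 ± 0.23. Of 22 cyclic AMP and CREB targets, 8 were higher and 6 lower (14 adjusted over the list alone; adjusted p = 0.947). Rgs2, a regulator of G protein signalling in vascular muscle, and the orphan receptor gene Nr4a1 were lower at -3.28 ± 0.30 and -2.14 ± 0.13, while Creb3l1 was higher at 1.90 ± 0.31 and the clock gene Per2 at 1.29 ± 0.10, with a second Per2 probe that did not pass. The median of this list was 0.02, its mean was -0.05 and camera and fry put it lower. That median was -0.15 with median centring (5 higher and 5 lower) and -0.10 with no filter on dim probes.

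Rap signalling genes were higher at 9 of 25 and lower at 3, Rap1a among the latter (12 adjusted over the list alone). The list was not called by camera (adjusted p = 0.361), but was by fry (0.00793), which put it higher. With median centring 5 were higher and 1 lower, and without replicate 1 the numbers were 10 and 6. Ralgds, an exchange factor for Ral that binds Ras and Rap, had 2.05 ± 0.14. Radil, a Rap effector, had 1.44 ± 0.36, and the cyclic AMP-activated Rap exchange factor gene Rapgef3 had 1.44 ± 0.38. Rassf5, another Rap effector, had 0.81 ± 0.16 and did not pass with median centring (adjusted p = 0.0540). Of the adrenoceptors, the Adra2c probe was not well above background in either channel on any array and was not tested. Among the 5 adrenoceptor genes tested, Adra1b and Adra2a were lower at -1.44 ± 0.33 and -0.86 ± 0.35, and a dim second Adra1b probe did not pass. Adra1d was higher at 0.42 ± 0.24, and did not pass when replicate 2, 3 or 4 was left out (adjusted p = 0.120, 0.101 and 0.0912). Over the list 2 genes were higher and 2 lower (4 adjusted over the list alone), and it was not called (adjusted p = 0.579). None was higher, and 2 were lower, with median centring or when replicate 2, 3 or 4 was left out. Of 16 ion channel and vascular tone genes, 4 were higher and 7 lower (13 adjusted over the list alone; adjusted p = 0.567), against 1 and 5 with median centring. The angiotensin receptor gene Agtr1a was higher at 3.37 ± 0.45 and the calcium channel gene Cacna1c at 0.93 ± 0.13, the latter not with median centring. The prostanoid genes Ptger4 and Ptgs1 were lower at -1.19 ± 0.22 and -0.97 ± 0.08.

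Metabolic and cell death groups were not called by camera either. Fry called oxidative phosphorylation (adjusted p = 0.00793) and lipid handling (0.00303) lower and p53 (0.0102) higher, but not hypoxia and glycolysis (0.316). Hypoxia and glycolysis genes were higher at 6 of 24 and lower at 9 (15 adjusted over the list alone; adjusted p = 0.590), with the lactate dehydrogenase gene Ldha lower at -1.23 ± 0.03 and Ndrg1, P4ha1 and Adm higher at 1.28 ± 0.13, 1.28 ± 0.25 and 1.19 ± 0.16. The median of that list was 0.02 and its mean -0.05, and camera and fry put it lower. With median centring 3 were higher and 10 lower, with a median of -0.48. Of 23 oxidative phosphorylation genes, 2 were higher and 7 lower (9 adjusted over the list alone; adjusted p = 0.303). Only 3 were lower without replicate 2 or 3, and 4 without replicate 4 or with the scanner software's ratios. Cox5a was lower at -0.51 ± 0.03, and the brightest Atp5b probe was lower at -1.08 ± 0.08 while 2 other probes of that gene did not pass. Sdha was higher at 0.80 ± 0.40, a second Sdha probe did not pass, and the first did not pass with median centring (adjusted p = 0.247). With that centring 14 were lower and none higher, and the list was called lower (median -0.66, adjusted p = 0.00226). Lipid handling genes were higher at 2 of 15 and lower at 7 (9 adjusted over the list alone; adjusted p = 0.0851). Ch25h, which makes 25-hydroxycholesterol, and the apolipoprotein gene Apoe were lower at -2.78 ± 0.23 and -1.91 ± 0.13, and the endocytic receptor gene Lrp1 was higher at 2.74 ± 0.23. Among 24 p53 and apoptosis genes, 8 were higher and 5 lower (16 adjusted over the list alone; adjusted p = 0.657). With median centring 3 were higher and 5 lower, and without replicate 2 the numbers were 4 and 4. The list held the death receptor gene Fas at 1.66 ± 0.16 and the BH3-only gene Pmaip1 at -2.32 ± 0.31. Gadd45b and Sesn1 of the same list were higher at 1.29 ± 0.22 and 1.25 ± 0.27, Sesn1 no longer with median centring (adjusted p = 0.0543).

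Pericyte markers were the other cell type list that was called, besides fibroblast markers. Of 6 tested, 5 were higher in the channel labelled RapCA and 1 lower (6 adjusted over the list alone), with a median of 2.03, a camera adjusted p of 0.0153 and an adjusted p = 0.463 with an estimated correlation. Notch3, Mcam, Anpep and Pdgfrb had 2.79 ± 0.50, 2.30 ± 0.30, 2.27 ± 0.37 and 1.78 ± 0.27, and 3 of the 6 markers also stand in other lists. With no filter on dim probes, which adds dim markers, the same numbers of markers passed and the median was 0.25. Endothelial markers went both ways, 4 of 9 higher and 3 lower (8 adjusted over the list alone, camera adjusted p = 0.980). Vwf and Plvap had -2.03 ± 0.16 and -1.49 ± 0.44, and Flt1 and Tek had 1.41 ± 0.34 and 1.16 ± 0.23. Tek was above background on 2 of 4 arrays in the channel labelled vector. The endothelial median was 0.25 and the mean -0.07, with camera putting the list higher and fry lower. That median was 0.58 with the scanner software's ratios, 0.031 with no filter on dim probes and -0.24 with both channels above background on all arrays. Of 6 macrophage and leukocyte markers, 1 passed, both over all probes and adjusted over the list alone: Lyz2, not well above background on any array in the channel labelled vector, was at least 1.42-fold higher in the other (adjusted p = 0.00411; list adjusted p = 0.544). Fcer1g, Cd3e and Cd14 had 0.15 ± 0.19, 0.11 ± 0.23 and 0.08 ± 0.21 and did not pass, though Cd3e passed without replicate 1 (adjusted p = 0.0267). Of 6 epithelial markers, 1 was higher and 2 lower (3 adjusted over the list alone, camera adjusted p = 0.267). Fry called that list lower (adjusted p = 0.0169). Krt8, not above background in the channel labelled RapCA, was at least 2.05-fold lower there, and Krt19 had -1.25 ± 0.59. Cldn7 had 0.43 ± 0.17 and passed, but not when replicate 2, 3 or 4 was left out (adjusted p from 0.0542 to 0.0917), and Krt5 had -0.16 ± 0.09 and did not pass, though it did with the scanner software's ratios (-0.95, adjusted p = 0.0171). Schwann and neural markers were higher at 3 of 7 and lower at 2 (6 adjusted over the list alone, camera adjusted p = 0.646), with S100b at 3.01 ± 0.45 and Tubb3 at 0.79 ± 0.45. The neurofilament genes Nefl and Nefm of this list had -4.86 ± 0.63 and -3.20 ± 0.80, both above background on 1 of 4 arrays in the channel labelled RapCA. The median of this list was 0.49 and its mean -0.44, with camera putting it higher and fry lower, and with no filter on dim probes the median was 0.038. Of 5 skeletal muscle markers, 3 were higher and 1 lower (5 adjusted over the list alone; adjusted p = 0.567), with the acetylcholine receptor gene Chrna1 at -2.12 ± 0.16 and the actin gene Acta1 at 0.84 ± 0.37. Tnni2 and Mylpf had 0.54 ± 0.36 and 0.33 ± 0.11 and passed, but not when replicate 2, 3 or 4 was left out (adjusted p from 0.0735 to 0.155). The median of the skeletal list was 0.33, its mean -0.03, and camera put it higher and fry lower. Its median was 0.014 with no filter on dim probes and 0.81 with the scanner software's ratios. Only 4 adipocyte markers were measured, too few for the list test. Pparg and Fabp4 were lower at -1.78 ± 0.11 and -1.44 ± 0.11, and Cebpa was higher at 1.69 ± 0.33 with a dim second probe that did not pass. Lpl had 0.18 ± 0.16 and did not pass; 3 of the 4 passed when adjusted over the list alone, and 3 also stand in other lists.

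**Figure D3:**
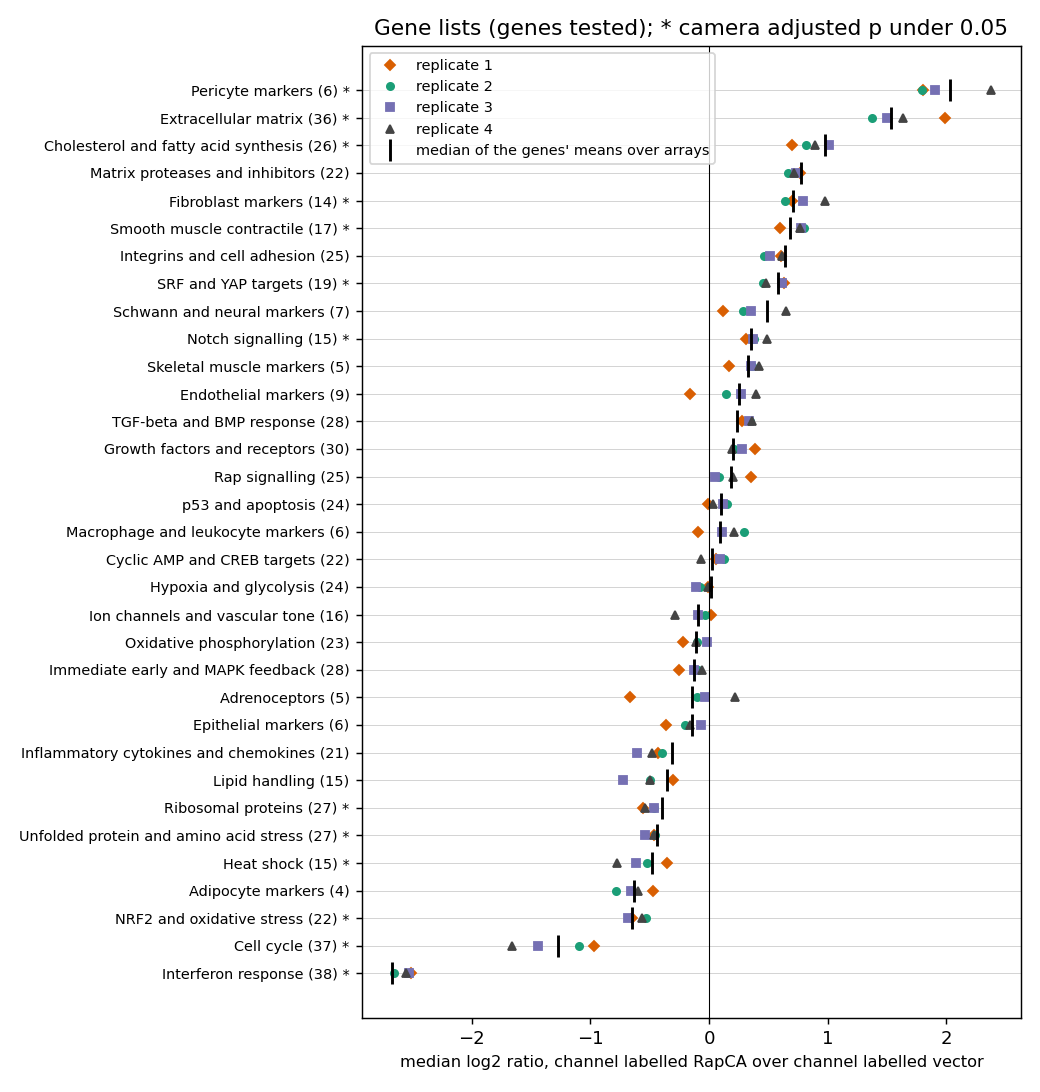
Median log2 ratio (channel labelled RapCA over channel labelled vector) of each gene list reported on each of 4 arrays, with black ticks for the median of the genes' means and an asterisk where camera with a preset correlation gave an adjusted p under 0.05. Interferon response lies lowest at -2.67 and pericyte markers highest at 2.03, or 0.25 with no filter on dim probes; none of the 13 marked lists passes with an estimated correlation.

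Other genes among the 15 largest rises were spread over several functions. Ccn5, a matricellular protein gene of smooth muscle, and Svep1, a large matrix adhesion protein gene, stood beside Mest, an imprinted gene expressed in mesoderm, at 3.92 ± 0.29. S100a16 had 3.70 ± 0.51, the semaphorin gene Sema3b had 3.45 ± 0.57 and Ecrg4 had 3.42 ± 0.60. Syt13 had 3.95 ± 0.40, but its second and dimmer probe did not pass (adjusted p = 0.877). All of these ratios include an offset added to both channels, which makes large folds and those of dim probes smaller than they were. The 4 arrays limit the precision, and p-values measure only the spread between these samples, which may be technical.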

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

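Of the tests in this part, those on Rap1a, on second probes and on exchanged channels were chosen after the result was seen. Each value below stood far from the other 3 arrays, with a gap to the nearest of them that took up most of the range. Chance alone gives this for about 1 in 20 groups, and 152 probes of named genes, 33 lists and 10 quality measures were examined. Replicate 1 was the distant array for 7 of the 13 probes. Its log2 ratios were 1.49 for an Flna probe (others 0.28 to 0.49) and 1.92 for another Flna probe (1.20 to 1.29). They were -5.69 for Oasl1 (-4.95 to -4.81), -4.75 for Sox12 (-3.78 to -3.65) and -1.09 for Ptgs1 (-0.94 to -0.92). Cd3e and Cldn7, which code for a T cell receptor chain and a claudin, had -0.23 (0.19 to 0.26) and 0.17 (0.51 to 0.53). The share of probes above background in Cy5 was 51.3% against 60.1% to 61.9%. Replicate 2 stood apart for Rtp4 at -5.17 (-4.53 to -4.42), Blnk at -4.30 (-4.57 to -4.55) and Fosl1 at -2.54 (-3.25 to -3.21). Replicate 3 did for Krt5 at -0.0209 (-0.21 to -0.19), Chrna1 at -2.35 (-2.06 to -2.01) and the median of the unfolded protein list at -0.54 (-0.46 each). Replicate 4 did for Anpep at 2.83 (2.02 to 2.15).

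Rap1a was lower in the channel labelled RapCA. The ratio nearest 0 over the other background corrections and centrings was -1.05, so the choice among these did not give the sign. Each of them centres the ratios on the bulk of probes, so an error of scale between the channels that all share was not tested. Spike-in medians of -1.95 on replicate 1 and -0.18 to 0.33 on the others were not used for scaling. Normalization therefore stays open. A dye bias of this probe stays open. Spike-in probes above background deviated from their own median by -1.41 to 0.56, so the Rap1a value lies within their range, although only 1 of 8 lay that far out. That range measures dye bias only if each spike-in was added equally to both channels, which is not known here. Dyes recorded the wrong way round could give the value of -1.07 as well. That cannot be told apart from correct labels here, because the position of the probe relative to the deletion, or to any sequence the vector carries, is not known. A vector that carries no sequence matched by the probe would also leave the labels unchecked, and this was not tested.

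The channels differed at a large part of the probes on all 4 arrays. For changes of at least 2-fold, bias of single probes to a dye as the main cause is argued against. Among genes whose brightest probe changed this much, a second probe went the same way in 96.3% (680 of 706). The exact 95% interval was 94.7% to 97.6%, and the second probe was itself called that way for 611. Most called probes changed by less than 2-fold. Among genes called with such a smaller change, a second probe went the same way in 87.4% (1622 of 1856). A bias shared by all probes of a gene was not tested, and without a dye exchange the design leaves it open. Probe sequences were not available, so whether the probes of a gene overlap, and could share a bias in that way, is not known. Of the 8 ways to exchange the channels of arrays, 1 gave as many called probes, the real one with 11654, and the highest other gave 0; 8 are too few for a share under 0.05. The biological difference that the labels name, the vector, stays open and follows the dye exactly.

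Replicate 1 stood apart from the other arrays, with a correlation of 0.747 with their mean against 0.905 to 0.965, a spike-in median of -1.95 against -0.18 to 0.33, and an array weight of 0.144. Weak Cy5 signal in dim spots as the whole cause is argued against, since the gap in correlation was 0.209 among the 25% brightest probes and 0.195 over all. No biological explanation was tested, because the labels give none.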

How the results depend on the processing

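All alternatives here were planned; for each change below whose source is not named, the cause was not tested. Signal over background limits dim probes, and the offset shrinks their ratios. The called probes numbered 6546 with median centring (2624 higher), 17694 with array weights (8641 lower), 12296 with separate channels and 10246 without pairing of channels, against 11654. Counted by genes, which are fewer than probes, they were 6666. Leave-one-out counts of called probes ran from 7912 to 15739 and of lower probes from 3526 to 7665, with 3625 without replicate 2. The 2-fold count was 5286 with the scanner software's ratios, 5283 with the series table and 3932 with an offset of 10; the first 2 also change background and dye normalization. Rap1a stayed below 0 under every alternative, from -1.33 to -0.93, except with signs turned, where it is 1.07 by construction. Lists called were 13, 0 with an estimated correlation and 26 with fry. The lists were not refitted with separate channels or without pairing. The Flna probe at 0.65 was -0.11 with median centring. Cd14 was -0.0494 with median centring and -0.00622 to 0.15 with an array left out. The cyclic AMP list median was -0.15 with median centring and -0.0536 to 0.11 with an array left out. The endothelial median was 0.16 without background correction, -0.24 with both channels above background, and 0.20 to 0.29 with an array left out. Over genes and alternatives 2365 results kept direction and call, 33 lost and 4 gained a call, and 3 turned; over lists, by camera's direction, 424, 8, 7 and 6. Medians could turn where that direction did not: with median centring Rap signalling had -0.07, p53 -0.19 and hypoxia -0.48, and adrenoceptors had 0.0271 without replicate 1.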

Other observations

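In this part the gene families were chosen after their values were seen, while the tests on Hox genes, Y-linked genes and clock phase were written down before the values they use. The rules that decide the Hox and clock tests were tightened after their values were seen. MHC class I genes, which interferon induces and the list did not hold, were lower in the channel labelled RapCA at all 11 tested, with H2-K1 at -2.74 ± 0.24, H2-Q4 at -2.55 ± 0.18 and H2-D1 at -2.31 ± 0.17; these are close relatives whose signals are not fully separate. All 4 alpha glutathione transferases were lower, Gsta1 at -3.94 ± 0.10 being above background on 1 of 4 arrays in that channel. The chromatin genes Hmga1 and Hmga2 were lower at -3.63 ± 0.23 and -2.88 ± 0.59. Among 10 clock output genes, 5 were higher and 1 lower, with Tef at 2.39 ± 0.21, Dbp at 2.32 ± 0.48, Per2 at 1.29 ± 0.10 (another probe did not pass) and Hlf at -1.21 ± 0.24.

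Different clock phases of the cultures could raise Dbp, Tef and Per2 together. Of genes that peak in antiphase, Nfil3 was lower at -1.15 ± 0.13 and Arntl had 0.43 ± 0.53 and did not pass, for a mean of -0.36 ± 0.21, while Npas2 was not measured. A mean below 0 by more than its SD met the criterion written before for a phase difference. The requirement that all 3 genes be present was added after the value was seen, and with it phase stays open.

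Cultures of different positional origin might differ in Hox genes. A change of at least 2-fold was found at 12.5% of these (3 of 24) against 16.8% of intensity-matched genes (permutation p = 0.793). A share at or below the matched one met the criterion written before against this idea. The demand that it be lower by more than its spread was added after the value was seen, and was not met (permutation p = 0.409 for a share this low). Of all sizes of change, 15 of the 24 passed, 8 higher and 7 lower, or 62.5% against 53.9% of all genes. These values therefore leave positional origin open. The series design text, however, describes the cells with RapCA as the same cells as those with the empty vector. Cultures from animals of different sex are argued against by the stated sex, male for all cells, and by 2 Y-linked genes. A Ddx3y probe and Eif2s3y were above background in both channels on all 4 arrays, with a largest ratio of -0.63. Other Y-linked probes were dim: Kdm5d was above background on 4 arrays in the channel labelled RapCA and 3 in the other, a second Ddx3y probe on 2 and 3, and both Uty probes on none. Xist was above background in neither channel.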
